A study of Mus musculus with 6 samples.

How the data were processed

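Polyadenylated RNA of whole dorsal root ganglia from adult mice was sequenced in 6 libraries, 3 labelled Pten heterozygous and 3 labelled wild type. Per the labels' protocols, ganglia along the whole rostro-caudal axis were dissected from 4 animals of each genotype, pelleted and snap frozen, and the messenger RNA was enriched by poly(A) selection, fragmented and copied into cDNA at a sequencing company. The labels do not say how the animals were divided over the libraries, so every p-value measures only the spread between these samples. By sex-specific genes, replicate 1 of each genotype came from other animals than replicates 2 and 3. The spread between replicates 2 and 3 may be technical.

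The deposited values were whole-number read counts per gene, not normalized, in 1 table per library with the gene's exon coordinates, strand and summed exon length per the file headers. A table of the whole series held the same counts with gene symbols, and 0 of its cells differed from the per-library tables. The submitters' processing notes name the mouse genome build GRCm38. The aligner, the counting program, their versions and the strand setting were not given in the sources used here. Reads of a gene and of an antisense partner, and reads shared by a gene and its near-identical copies, could therefore not be told apart. Ribosomal protein genes have many processed pseudogenes, the zinc finger genes of chromosome 4 and the alpha globin genes have close copies, and the protocadherin alpha genes share exons, so values of these genes are uncertain. Of the 49315 gene identifiers, 49056 were found in GENCODE release M21 on the same build, and 91.4% of these had the same start and end. GC content came from that annotation and the GRCm38 sequence. Symbols came from the series table, in which 174 genes, with 0.0140% of the counts, had none.

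Libraries were assigned to genotypes by their labels alone. Total counts ran from 15429080 to 26755740 per library. A count of 0 in a library was read as a level of up to 3 counts, which is 0.112 to 0.194 CPM (the usual counts scaled to a common library total), and a fold against a group with 0 counts in all 3 libraries used 3 counts over the group. Such limits cover counting error only. The counts of each pair of the 6 libraries were compared by chi-square over genes, and the smallest chi-square per degree of freedom was 12.0, so no library was a duplicate of another within sampling noise.

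Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 17013 genes, and libraries were scaled by TMM. Differences were tested with the quasi-likelihood F test with robust estimation, genotype being the only term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Log2 fold changes are the libraries labelled Pten heterozygous minus those labelled wild type, and errors beside them are standard errors. CPM values are means ± SD of 3 libraries.

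A total of 32 gene lists, covering neuron classes, glia, other cell types of the dissected tissue, signalling pathways, cell states and autism risk, were fixed in advance, together with the tests, most of the other settings tried and the rule for named genes. List tests used camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists, and were repeated with an estimated correlation and with fry. The quasi-likelihood p-values of a list's members were also adjusted over the list alone. The rule named Pten first. It then took the 12 genes with the largest difference in each direction among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, and filled a short list with the smallest unadjusted p in that direction. Predicted models, pseudogenes and sex-specific genes were left out. Up to 4 members of each list with the smallest unadjusted p were added, with the sex-specific genes and the genes of library checks. Other genes are named as chosen after their values were seen.

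The tests were tried on simulated counts for the 17013 genes in 3 against 3 libraries, drawn from the real means, library sizes and dispersion, with 200 genes changed. The quasi-likelihood test recovered 17.9% of the genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold, and 7.58% of its calls were false. DESeq2 1.42.0 recovered 32.8%, 80.6% and 95.5%, and 15.8% of its calls were false. This was a single draw with genes independent of each other and no length trend, unlike the real counts.

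Other settings, chosen before the data were examined, were other scalings (DESeq2's size factors, upper quartile, library totals), DESeq2 and limma-voom as the test, no filter on low counts or at least 1 CPM in 3 libraries, each library left out in turn, the replicate number as a block, the series table as the source, no robust estimation, and the fit without muscle, blood, fat, bone, sex-specific and mitochondrially encoded genes. Chosen after seeing the data were a fit with sex as a factor, a correction for gene length and GC content fitted per library by loess (span 0.3), the bias-adjusted version of the quasi-likelihood test, a fit without the 2 libraries that held sympathetic neuron markers, and the lists with Tafa4, Drgx and Ccn1, which the series table holds under older symbols and the lists otherwise lacked. Reads, splice junctions and single exons were not analysed here.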

Results

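The series compared gene expression in dorsal root ganglia, which hold the cell bodies of the somatosensory neurons and their satellite glia, between adult mice labelled wild type and mice labelled heterozygous for Pten. Pten encodes a lipid phosphatase that opposes PI3K signalling, and the heterozygous mouse is used as a model of autism spectrum disorder. There were 3 libraries of each genotype. Total counts ran from 15429080 to 16948666 in the libraries labelled Pten heterozygous and from 17590479 to 26755740 in those labelled wild type, so every library of the first group was shallower than every library of the second. Of 49315 genes, 31306 had at least 1 count and 17013 were tested. Replicate 1 of each genotype came from female tissue, with 4850 and 6195 counts of Xist and 0 counts of Ddx3y, Uty, Kdm5d and Eif2s3y together. The other 4 libraries came from male tissue, with 2884 to 3581 counts of these 4 Y-linked genes and at most 12 of Xist.

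Pten itself was measured first, as the check of the labels, and it went against them. Its level was 246, 326 and 362 CPM in the libraries labelled Pten heterozygous and 185, 166 and 181 CPM in those labelled wild type. The means were 311 ± 59.3 and 178 ± 10.1 CPM (SD, n = 3 each), a 1.75-fold higher level in the libraries labelled Pten heterozygous (log2 fold change 0.81 ± 0.14, SE). All 3 libraries of that group lay above all 3 of the other. The difference did not pass edgeR's quasi-likelihood test over all genes (adjusted p = 0.184), and it did with DESeq2 (adjusted p = 2.74e-05), without replicate 1 labelled Pten heterozygous (edgeR adjusted p = 0.0241) and with no filter on low counts (adjusted p = 8.04e-08). The last fit had 634 prior degrees of freedom against 5.98 with the filter, so each gene's spread was almost the pooled one, and its p is not comparable. Over all fits run its adjusted p ran from 8.04e-08 to 0.643. An exact permutation test of Pten alone gave p = 0.1 (two-sided), the smallest that 3 against 3 libraries allow. Pten (ENSMUSG00000013663) lies on chromosome 19 from 32757497 to 32826160 in GRCm38, and its exons sum to 11507 bases. The counts cover all of its exons together, and the labels do not state which part the mutant allele lacks, so a transcript from the mutant allele could not be separated. Since the targeted gene goes against the labels, directions below are given for libraries as labelled.

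**Figure D1:**
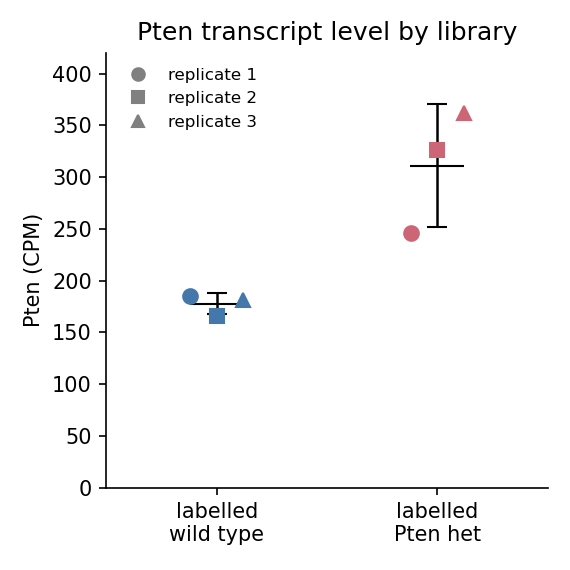
Pten level in CPM (vertical axis) in each library, by labelled genotype. Symbols are libraries, with replicate numbers as in the legend, and bars are the mean ± SD of 3 libraries. The libraries labelled Pten heterozygous lie at 246 to 362 CPM and those labelled wild type at 166 to 185 CPM.

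Over all genes, the difference nearest to the threshold was that of Akr1e1, an aldo-keto reductase gene, at 19.7 ± 0.199 CPM in the libraries labelled Pten heterozygous against 7.20 ± 1.28 CPM in those labelled wild type (2.75-fold higher, log2 fold change 1.46 ± 0.16, edgeR adjusted p = 0.0693). Among the other higher genes named by the rule were the growth factor gene Fgf2 (1.51-fold) and Ccng1, a p53-responsive cyclin gene (1.48-fold). They also included the phosphatase genes Dusp19 (1.61-fold) and Ppp2r3a (1.50-fold), the nuclear pore gene Nup153 (1.39-fold) and the helicase gene Smarcal1 (1.34-fold). Swt1, Slc12a3, Pcdha4 and Dmkn were 1.88-fold, 1.81-fold, 2.76-fold and 5.16-fold higher, the last at 3.45 ± 2.20 against 0.673 ± 0.156 CPM. Among the 12 lower genes with the smallest p that met the rule's conditions, 9 encoded cytosolic ribosomal proteins. Zfp990, chosen after its values were seen and under the rule's minimum of 1 CPM, had a smaller unadjusted p by edgeR (1.73e-05). That of Rpl37, the smallest of the 12, was 9.81e-05. Rpl37 was 2.13-fold lower, Rpl35a 1.95-fold, Rpl31 and Rps23 both 1.85-fold, Rpl36a 1.77-fold, Rps17 1.75-fold, Rpl32 1.70-fold, Rps15 1.61-fold and Rps14 1.50-fold. The remaining 3 were Zfas1, a noncoding RNA that hosts small nucleolar RNAs (1.90-fold lower), the imprinted gene Ndn (1.66-fold lower, 142 ± 6.74 against 236 ± 37.7 CPM) and Inafm1 (1.60-fold lower). All 12 genes of each direction had groups that did not overlap, and their adjusted p by edgeR ran from 0.0693 to 0.232, so none passed by edgeR. DESeq2 called 22 of these 24 genes over all genes, all but Dmkn and Pcdha4. It gave an adjusted p to 13631 genes, and a gene without one counts as not called. Dmkn and Pcdha4 thus either failed or had none.

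With edgeR's quasi-likelihood test 0 genes were higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 2334 genes, 849 higher and 1485 lower, where chance gives 851. With the correction for gene length and GC content, chosen after seeing the data, edgeR gave 1403 such genes, so part of the excess went with these features. DESeq2 called 37 genes higher and 229 lower among the 13631 genes to which it gave an adjusted p. Of these calls 54 lower and 0 higher ones were ribosomal protein genes by symbol, and limma-voom called 0 and 1. The 37 included Slc6a2, Dbh and Ddc, chosen after their values were seen, whose counts were high in only 2 of the 3 libraries labelled Pten heterozygous. Groups that did not overlap were seen for 3399 genes, 19.98% of those tested, where chance gives 10%. Without replicate 1 labelled Pten heterozygous edgeR called 78 genes higher and 140 lower, without replicate 2 of that label 10 and 0, without wild type replicate 1 5 and 0, and with no filter on low counts, where the spread was almost wholly pooled, 124 and 347.

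The cytosolic ribosomal protein genes were lower as a group in the libraries labelled Pten heterozygous. All 40 measured genes had a lower estimate, with a median log2 fold change of -0.56, which is 68.0% of the level in the libraries labelled wild type. By edgeR 35 of the 40 fell and 0 rose adjusted over the list alone, against 0 over all genes tested, where DESeq2 called 30 lower. The groups did not overlap for 35 of the 40, where chance gives 10% for a single gene and 19.98% of all tested genes had such groups. The members vary together (estimated inter-gene correlation 0.66), so the 35 are not independent results. Rpl37 stood at 50.6 ± 12.3 against 108 ± 10.99 CPM, Rps23 at 89.5 ± 19.3 against 166 ± 16.7, Rps15 at 140 ± 22.1 against 227 ± 16.1 and Rps14 at 189 ± 19.5 against 284 ± 16.7. The list was called by camera with the preset correlation (adjusted p = 4.71e-24) and not with an estimated one (adjusted p = 0.927 with an estimated correlation), nor by fry (adjusted p = 0.215). The list mean per library, centred on all 6, was -0.13, -0.29 and -0.45 in the libraries labelled Pten heterozygous and 0.26, 0.44 and 0.18 in those labelled wild type. These genes are short, with a median length of 1800 bases, and short genes as a whole had lower estimates in the libraries labelled Pten heterozygous, as described below for gene length.

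Nuclear-encoded genes of oxidative phosphorylation, a list of respiratory chain and ATP synthase members, were lower as a group as well. Its ATP synthase members Atp5a1, Atp5b and Atp5c1 moved little, with log2 fold changes of -0.06, -0.12 and 0.03. Of 41 measured members 38 had a lower estimate, with a median log2 fold change of -0.26 (83.6% of the level in the libraries labelled wild type), and 18 fell by edgeR adjusted over the list alone, against 0 over all genes, where DESeq2 called 14 lower. With 1 library left out the median ran from -0.33 to -0.14, the latter without wild type replicate 2. Ndufa2, a subunit of complex I, was 2.06-fold lower (27.9 ± 7.55 against 57.6 ± 12.1 CPM). The cytochrome oxidase genes Cox7b and Cox7c were 1.62-fold and 1.73-fold lower, and Uqcrq, of complex III, was 1.71-fold lower. Camera called the list with the preset correlation (adjusted p = 1.68e-07), and the call was lost with adjusted p = 0.927 with an estimated correlation. The count of 18 went to 0 without replicate 2 or replicate 3 labelled Pten heterozygous or without wild type replicate 2. The median length of these genes was 1718 bases.

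Protein genes encoded by the mitochondrial genome had the opposite sign. Of 13 measured genes 12 were higher, with a median log2 fold change of 0.35, and camera called the list (adjusted p = 0.00286, and adjusted p = 0.927 with an estimated correlation). Adjusted over the list alone 0 genes passed by edgeR, as over all genes by edgeR and DESeq2. With 1 library left out the median ran from 0.25, without replicate 2 labelled Pten heterozygous, to 0.67, without wild type replicate 2, and it was 0.09 after a correction for gene length and GC content. The abundant transcripts mt-Co1 and mt-Nd2 stood at 14270 ± 2760 against 10687 ± 2936 CPM and 2047 ± 401 against 1509 ± 437 CPM, and the libraries of the groups overlapped. Mitochondrially encoded transcripts took 2.60%, 3.75% and 3.11% of the counts of the libraries labelled Pten heterozygous and 2.15%, 3.14% and 2.17% of those labelled wild type. The camera call at the preset correlation was lost without replicate 2 labelled Pten heterozygous (adjusted p = 0.0602), without wild type replicate 1 (adjusted p = 0.0551) or replicate 3 (adjusted p = 0.0510), and after the length and GC correction (adjusted p = 0.122). The last was the highest camera value at that correlation, and the lowest was 2.95e-08 without wild type replicate 2.

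Markers of skeletal muscle, a tissue next to the ganglia, were higher in the libraries labelled Pten heterozygous, and their level varied widely between libraries. All 15 genes had a higher estimate with a median log2 fold change of 1.44, and 0 passed by edgeR adjusted over the list alone, or by edgeR or DESeq2 over all genes. With 1 library left out the median ran from 0.63, without replicate 2 labelled Pten heterozygous, to 1.96, without wild type replicate 3. Atp2a1, the calcium pump of fast muscle, stood at 591 ± 424 against 168 ± 121 CPM, and the titin gene Ttn at 368 ± 376 against 102 ± 83.2 CPM. The list mean was 0.94, 2.11 and -0.62 in the libraries labelled Pten heterozygous and -3.02, 0.28 and 0.31 in those labelled wild type, so the groups overlapped. Camera called the list (adjusted p = 0.00116, and adjusted p = 0.927 with an estimated correlation). The call was lost without wild type replicate 1, the library with the least muscle RNA (adjusted p = 0.155), and without replicate 1 (adjusted p = 0.0660) or replicate 2 (adjusted p = 0.0676) labelled Pten heterozygous. In the other fits with the preset correlation its adjusted p was as low as 9.45e-07.

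**Figure D2:**
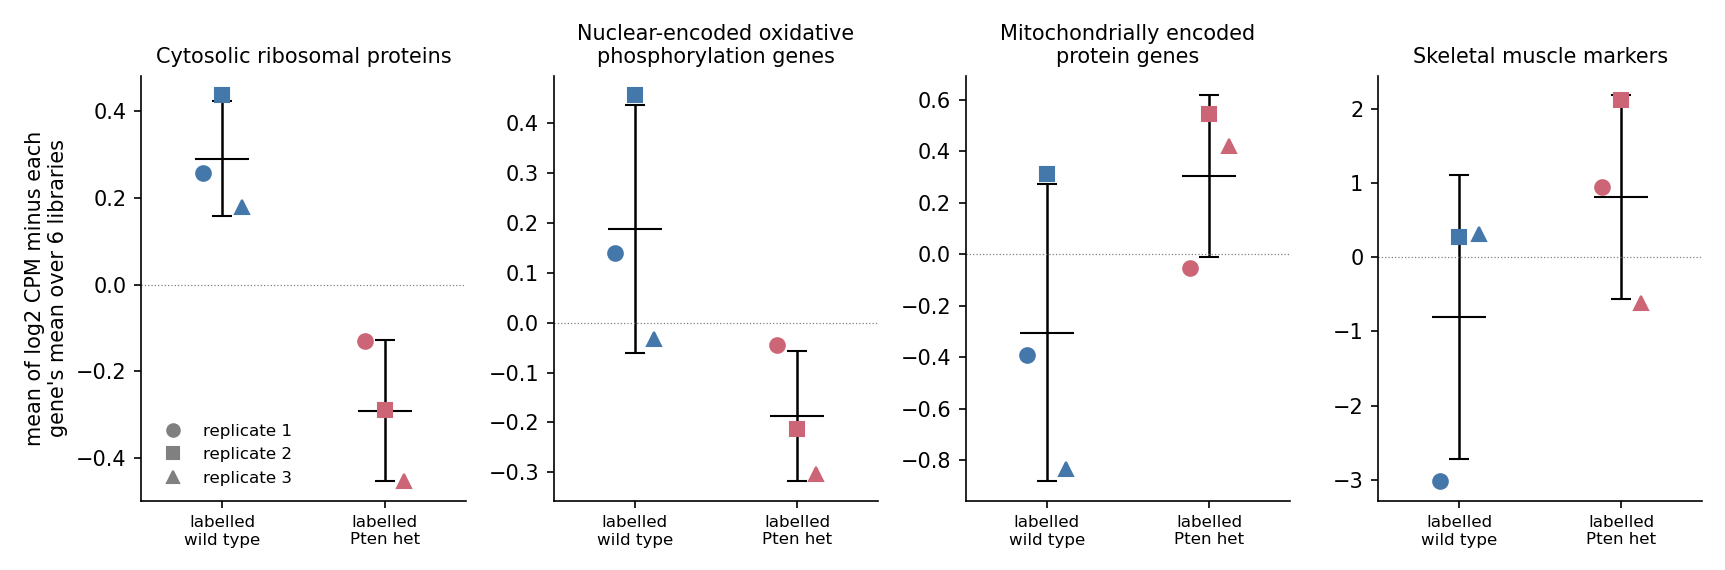
Mean level of 4 gene lists in each library (vertical axes, log2 CPM minus each gene's mean over the 6 libraries, with a scale of its own in each panel), by labelled genotype. Symbols are libraries and bars are the mean ± SD of 3 libraries. The groups are apart for ribosomal protein genes (-0.45 to -0.13 against 0.18 to 0.44). They are narrowly apart for oxidative phosphorylation genes (-0.303 to -0.045 against -0.033 to 0.456) and overlap for mitochondrially encoded genes and muscle markers.

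Autism risk genes were higher by a small amount. Of 29 measured genes 22 had a higher estimate, with a median log2 fold change of 0.12 (1.09-fold), and camera called the list (adjusted p = 0.0426, and adjusted p = 0.927 with an estimated correlation). Fmr1, the gene of fragile X syndrome, was 1.28-fold higher in estimate at 71.7 ± 11.6 against 56.1 ± 1.55 CPM, Setd5 stood at 125 ± 5.32 against 105 ± 8.18 CPM and Ube3a at 114 ± 36.7 against 80.2 ± 2.84 CPM. Adjusted over the list alone 0 genes passed by edgeR, as over all genes by edgeR and DESeq2. These genes are long (median 12732 bases), and the call was lost after a correction for gene length and GC content (median log2 fold change -0.01, adjusted p = 0.905). It was also lost, with medians that stayed at 0.11 to 0.17, without replicate 1 (adjusted p = 0.205) or replicate 2 (adjusted p = 0.106) labelled Pten heterozygous, without wild type replicate 1 (adjusted p = 0.0564) or replicate 2 (adjusted p = 0.279), without both libraries that held sympathetic neuron markers, which leaves 1 library against 3 (adjusted p = 0.0887), and without muscle, blood, fat, bone, sex-specific and mitochondrially encoded genes (adjusted p = 0.0531), and the lowest value was an adjusted p = 0.00342 without wild type replicate 3.

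Small differences varied with gene length. Across the 17013 tested genes, which are not independent replicates, the log2 fold change increased with length (Spearman's rho = 0.264). The median log2 fold change was -0.15 in the decile of genes with the shortest transcripts (median 928 bases) and 0.13 in the decile with the longest (median 11338 bases). Within the shortest decile 337 genes were lower and 63 higher at an unadjusted p under 0.05, and within the longest decile 10 were lower and 158 higher. The trend was not the same in all libraries of a genotype. The correlation of a library's centred level with length across genes was 0.03, 0.21 and 0.17 in the libraries labelled Pten heterozygous and -0.17, -0.35 and 0.02 in those labelled wild type, so wild type replicate 3 lay close to replicate 1 labelled Pten heterozygous.

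**Figure D3:**
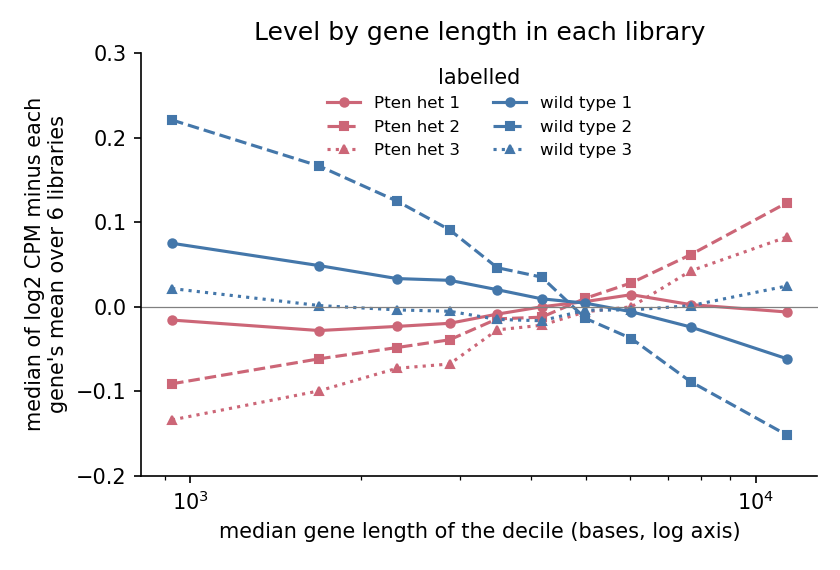
Median level (log2 CPM minus each gene's mean over the 6 libraries, vertical axis) of genes in 10 classes of gene length (horizontal axis, bases, log scale), 1 line per library, coloured by labelled genotype. For the shortest genes wild type replicate 2 lies highest (0.221) and replicate 3 labelled Pten heterozygous lowest (-0.134). For the longest genes wild type replicate 2 lies lowest (-0.152) and replicate 2 labelled Pten heterozygous highest (0.123).

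None of the lists of sensory neuron classes was called by camera, and by edgeR 0 of their genes passed, either adjusted over the list alone or over all genes. DESeq2 called 1 of them over all genes, Tlx3, as lower. Markers of non-peptidergic nociceptors had a median log2 fold change of 0.06, with 12 of 14 genes higher in estimate, among them Mrgprd, a receptor of polymodal nociceptors of the skin (157 ± 5.73 against 126 ± 15.3 CPM), and Cd55 (421 ± 79.4 against 355 ± 0.469 CPM). Peptidergic nociceptor markers had a median of 0.11, with Kit at 92.2 ± 5.79 against 82.1 ± 5.27 CPM and Gal at 12.7 ± 1.89 against 16.5 ± 3.02 CPM. Markers of C-low-threshold mechanoreceptors and cold-sensing neurons had a median of 0.21, and their list mean kept the groups apart (0.10, 0.11 and 0.07 against -0.01, -0.14 and -0.13), with an adjusted p = 0.237 by camera. The cold receptor gene Trpm8 of this list stood at 47.4 ± 4.29 against 37.9 ± 5.82 CPM. List means kept the groups apart for 3 of the 32 lists, where chance gives 10%. Pruriceptor markers had a median of 0.10, with Osmr at 54.4 ± 9.70 against 47.0 ± 3.29 CPM. Markers of large-diameter mechanoreceptors and proprioceptors had a median of -0.08, and the potassium channel subunit gene Kcns1 (53.2 ± 8.83 against 74.5 ± 4.33 CPM, adjusted p = 0.0724 over the list alone) and Necab2 (12.8 ± 0.862 against 18.4 ± 3.67 CPM) were lower in estimate. Genes shared by all sensory neurons had a median of -0.18, with 11 of 16 lower in estimate, including the transcription factor gene Tlx3 (56.7 ± 9.51 against 82.5 ± 11.3 CPM). Among 37 ion channels and receptors of transduction and excitability the median was 0.07, with Kcnq3 at 57.0 ± 6.60 against 44.7 ± 1.04 CPM and Hcn2 at 76.8 ± 8.42 against 98.7 ± 9.24 CPM. Without wild type replicate 2 camera called the peptidergic list higher, and without wild type replicate 3 it called the genes of all sensory neurons lower.

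Glial lists were not called either. Of the satellite glia markers, which had a median log2 fold change of 0.11 with 8 of 13 higher in estimate, the lipid carrier gene Apoe, which macrophages also make, fell in the libraries labelled Pten heterozygous, 1.45-fold (1620 ± 232 against 2345 ± 352 CPM, edgeR adjusted p = 0.0488 over the list alone, adjusted p = 0.247 over all genes), and was the only 1 of 13 members to pass adjusted over the list alone, with 0 over all genes by edgeR, while DESeq2 called Apoe over all genes too. The potassium channel gene Kcnj3 of the list stood at 24.9 ± 2.36 against 19.8 ± 1.59 CPM. Myelin and Schwann cell genes had a median log2 fold change of -0.19 with 14 of 19 lower in estimate, among them Mpz, the main protein of peripheral myelin (3892 ± 305 against 5189 ± 809 CPM), Mag (61.5 ± 8.45 against 76.0 ± 2.12 CPM) and Cnp (285 ± 12.1 against 343 ± 30.4 CPM), and 0 passed over the list alone by edgeR, or over all genes by edgeR or DESeq2. Camera called this list lower without wild type replicate 2. Genes of non-myelinating and repair Schwann cells had a median of -0.02 and a mean of 0.04, with camera's direction lower, and Cdh19 stood at 119 ± 24.9 against 83.3 ± 8.63 CPM.

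Among components of the PI3K, AKT and mTOR pathway 2 of 35 genes passed by edgeR adjusted over the list alone and 0 over all genes, and DESeq2 called the same genes over all genes. Pten was 1 of these (edgeR adjusted p = 0.00568 over the list alone), higher in the libraries labelled Pten heterozygous. The other was Rps6, a ribosomal protein and a substrate of S6 kinase, at 159 ± 11.3 against 216 ± 16.8 CPM (1.36-fold lower, adjusted p = 0.0227 over the list alone), which moved with the other ribosomal protein genes. The list median was 0.06 and camera did not call it (adjusted p = 0.492). Of 20 FOXO target genes, Pik3ip1, an inhibitor of PI3K, fell 1.36-fold adjusted over the list alone (82.0 ± 3.59 against 111 ± 6.25 CPM, edgeR adjusted p = 0.0165) and 0 passed over all genes by edgeR, while DESeq2 called Pik3ip1 there. The list median was 0.13, and Klf15 stood at 16.2 ± 4.37 against 10.2 ± 2.30 CPM. Targets of SREBP and genes of sterol and fatty acid synthesis had a median of 0.08, with Idi1 at 76.8 ± 18.9 against 53.5 ± 3.96 CPM and Srebf1 at 88.2 ± 10.8 against 113 ± 9.25 CPM. Targets of ATF4 had a median of -0.05, with Slc3a2 at 116 ± 1.50 against 136 ± 8.93 CPM, and genes of glycolysis and hypoxia a median of -0.04. In these 3 lists 0 genes passed over the list alone by edgeR, or over all genes by edgeR or DESeq2.

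Lists of cell states gave no call. Immediate early genes had a median log2 fold change of -0.16, with 14 of 18 lower in estimate, among them Junb (15.2 ± 2.68 against 23.6 ± 4.14 CPM) and Fosb (1.17 ± 0.234 against 1.95 ± 0.0954 CPM), and camera's adjusted p was 0.169. Without wild type replicate 1 or replicate 3 labelled Pten heterozygous camera called this list lower, as it did with sex as a factor. Axon injury and regeneration genes had a median of -0.05 and a mean of 0.10 with camera's direction higher. The median was 0.01 for cell cycle genes, with a mean of -0.06 and camera's direction higher, and 0.05 for interferon-stimulated genes. No gene of these 4 lists passed over the list alone by edgeR, or over all genes by edgeR or DESeq2. Camera called cell cycle genes higher without wild type replicate 3.

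Markers of other cell types varied between libraries of the same genotype by more than between the genotypes, and 0 of their genes passed by edgeR over the list alone or over all genes. DESeq2 called Cd74 and Cldn5 lower over all genes. Blood and bone marrow markers had a median of -0.54 with all 17 lower in estimate, and their list mean was -0.09, 0.27 and -0.78 in the libraries labelled Pten heterozygous and 0.11, -0.78 and 1.27 in those labelled wild type. The alpha globin gene Hba-a2 stood at 10.4 ± 8.66 against 25.7 ± 6.37 CPM. The list mean of adipocyte markers ranged from -2.25 to 2.34, both in libraries labelled wild type, and their median of -0.19 and mean of -0.18 were of the opposite sign to camera's direction. The median was -0.10 for macrophage markers, with Cd74 at 47.3 ± 6.41 against 78.2 ± 19.3 CPM, and -0.06 for endothelial markers, with Cldn5 at 35.5 ± 11.1 against 57.6 ± 6.46 CPM. It was -0.14 for fibroblast, meningeal and mural cell markers, -0.05 for bone and cartilage markers, 0.10 for spinal cord markers and 0.44 for sex-specific genes, which follow the sex of each library. Without wild type replicate 2 camera called the lists of macrophages, blood and bone marrow, and fibroblasts lower and that of adipocytes higher, and without replicate 3 labelled Pten heterozygous it called spinal cord markers higher. With sex as a factor it called the sex-specific genes.

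The libraries did not separate by genotype along the main axes of variation. The first principal component of log2 CPM took 30.2% of the variance and placed replicate 1 labelled Pten heterozygous (-8.22) between wild type replicates 2 (-22.9) and 3 (2.68). Correlations of log2 CPM across genes were 0.976 to 0.981 between libraries of a genotype and 0.968 to 0.982 between genotypes. The biological coefficient of variation was 0.191.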

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

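The fits with sex as a factor, with the correction for length and GC content, with the bias-adjusted quasi-likelihood test, with older symbols of list members and without the 2 libraries holding sympathetic neuron markers were chosen after seeing the data, and the rest were planned. Pten was higher in the libraries labelled Pten heterozygous in every fit run. It passed the threshold with DESeq2 (log2 fold change 0.82) with no filter on low counts (0.82) and without replicate 1 labelled Pten heterozygous (0.95), and its estimate ran from 0.69 to 0.95 with 1 library left out. Counts of genes higher and lower moved from 0 and 0 to 37 and 229 with DESeq2, 124 and 347 with no filter (634 prior degrees of freedom against 5.98), and 1 and 5 with the replicate block. They were 0 and 1 with limma-voom, 1 and 0 at an adjusted p under 0.1, and 1 and 0 without the 2 libraries holding sympathetic neuron markers, a fit of 1 library against 3 that assumes the lone library varies like the others. With 1 library left out they ran from 0 to 78 higher and from 0 to 140 lower. The cause of these changes was not tested. Simulated data gave 15.8% false calls for DESeq2 against 7.58% for edgeR. With genes drawn independently and no length trend, these shares need not hold for the real counts. Lists past the threshold went from 5 to 0 with an estimated correlation, 0 with fry, 2 without muscle, blood, fat, bone, sex-specific and mitochondrial genes, where 2 of the 5 were left out by construction, and 3 with the length and GC correction. They were 4 with the replicate block, without autism risk genes (adjusted p = 0.0746), and ran from 2 to 10 with 1 library left out. The median of autism risk genes reversed to -0.0078 with that correction. Ribosomal protein genes lower over their list alone numbered 31 to 35 in all fits run and 33 to 35 with 1 library left out. For oxidative phosphorylation genes the count was 3 in that fit of 1 against 3 (median -0.30) and ran from 0 to 20 with 1 library left out. Of the fits of the other named genes 443 kept their side of the threshold, 63 passed it and 0 changed sign. The shared replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.12, -0.14 and -0.19, and not every library correlated best with its own number. Depth limits genes with few counts, and changes of 1.5-fold were mostly out of reach, with 17.9% recovered in simulated data.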

Other observations

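The tests of an exchange of libraries or labels, of Slc6a2 in replicate 2 and of chromosome 4 were chosen only after the values they use had been seen, as were Zfp990, Zfp985, Zfp991, Znf41-ps, Masp2, Sgk1, Npy, Dbh, Slc6a2, Ddc, Slc18a2 and Chrna3. Large differences gathered in a cluster of zinc finger genes on chromosome 4. Zfp990, at 145510759 to 145539188, had 0 counts in all 3 libraries labelled Pten heterozygous and 46, 34 and 52 in those labelled wild type, at least 30.9-fold lower against a floor of 3 counts over the group. Zfp985 had 0, 0 and 1 counts against 22, 21 and 15. Zfp991 was 3.00-fold higher and the pseudogene Znf41-ps 2.78-fold higher, and Masp2 was 5.01-fold lower. None of the 5 passed edgeR's test over all genes (adjusted p 0.147 to 0.247), while DESeq2 called Zfp991 alone of them (adjusted p = 0.00192). DESeq2 gave no adjusted p to 17675 genes, which count as not called, so the others may have gone untested there. Of 43 genes with a log2 fold change of at least 1 either way and an unadjusted p under 0.005, the densest run anywhere in the genome was here, with 4 (Zfp990, Znf41-ps, Zfp991 and Zfp985) among 6 neighbouring tested genes. A run as dense anywhere in the genome was seen in 0 of 10000 random gene sets, which argues against a random scatter over the genome. Animals of the labelled groups may carry different strain haplotypes there, which was not tested. Near copies of these zinc finger genes make their values uncertain, and reads shared between them could also move neighbours together. Sgk1, a kinase of the PI3K pathway, stood at 47.5 ± 15.9 against 25.03 ± 0.896 CPM and did not pass with edgeR (adjusted p = 0.232), while DESeq2 called it (adjusted p = 0.00108).

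The first pattern weighed is the level of Pten, higher in the libraries labelled Pten heterozygous. Among 500 genes matched to Pten on summed exon length, GC content and expression its log2 fold change lay at percentile 99.8 (median of the matched genes 0.21). This argues against a bias with summed exon length or GC content as the whole cause. The correction for both lowered the estimate from 0.81 to 0.55. An exchange of 1 library between the groups needs a library of each group out of place, and 0 libraries lay inside the other group's range of Pten CPM. This separation had been seen and had prompted the idea. It also marks the genotype only if the Pten level does, so it cannot decide on such an exchange. An exchange of the labels of the whole groups cannot be told apart from a real difference: the ratio of wild type to heterozygous Pten was 0.571 (95% interval 0.437 to 0.745), which includes the 0.5 of a lost allele, and 0.685 (0.589 to 0.797), which does not, with the length and GC correction, and the first value had prompted the idea. A mutant allele that yields a stable transcript also stays open, because the counts cover all exons together.

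The second pattern is the lower level of ribosomal protein and oxidative phosphorylation genes, with the higher level of autism risk genes. Against 10000 lists matched on summed exon length, GC content and expression, the ribosomal median of -0.56 lay at percentile 0 (matched median -0.15). The oxidative phosphorylation median of -0.26 lay at percentile 0.03 (matched median -0.13). Genes of like summed exon length and GC content thus moved less than either list. Members of a list vary together (estimated inter-gene correlation 0.66 and 0.77) while matched genes were drawn singly, so these percentiles do not measure chance. Matched genes were longer (median 2082 against 1800 bases, and 1894 against 1718), and summed exons can exceed the transcript present. A bias with transcript length is therefore not excluded for either list. With the correction for length and GC content camera still called the 2 lists at its preset correlation (medians -0.39 and -0.21, adjusted p = 2.18e-27 and 4.74e-07). Neither call held at an estimated correlation (adjusted p = 0.962 for both, and 0.927 without the correction) or by fry (adjusted p = 0.0932 and 0.999, and 0.215 and 0.786 without the correction). The autism median of 0.12 lay at percentile 48.2 (matched median 0.12), consistent with a length and GC bias between libraries. A difference in depth, which also separates the groups, in RNA quality or in library preparation that acts on these transcripts, and the genotype, stay open and untested for the first 2 lists.

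The third pattern is noradrenergic genes in 2 libraries labelled Pten heterozygous: counts of Dbh, which makes noradrenaline, were 833, 0 and 347 in the libraries labelled Pten heterozygous and 0, 1 and 1 in those labelled wild type, and those of the noradrenaline transporter gene Slc6a2 were 2196, 6 and 879 against 19, 18 and 19. Npy, a neuropeptide of these neurons and a member of the axon injury list, had 118, 4 and 101 counts against 5, 11 and 10. Th, another gene of noradrenaline synthesis, looked at after the data were seen, did not follow this pattern. It stood at 129, 86.6 and 99.1 CPM against 100, 102 and 75.3, and it is also a marker of C-low-threshold mechanoreceptors. The summed CPM of Hand2, Hand1, Phox2a, Phox2b and Gata3, markers listed before their values were seen, was compared. It was 25.9 times as high in the lower of replicates 1 and 3 as in the highest other library. Sympathetic ganglion neurons carried over in dissection could give this. DESeq2 called Slc6a2, Dbh and Ddc higher, edgeR none of those it tested, and of the 10 markers on this list 3, Ddc, Slc18a2 and Chrna3, had at least 32 counts in every library, so the ganglia also express them. Hand2, Hand1, Phox2a, Phox2b and Gata3 together had 1 count in replicate 2 labelled Pten heterozygous, against 5, 10 and 10 in the libraries labelled wild type. A rise in every library labelled Pten heterozygous was thus not seen. Whether the genotype acts on these genes stays open, since that rests on 1 library. Slc6a2 at 0.388 CPM in replicate 2, under every library labelled wild type, is 6 counts and had been seen.

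Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 0 genes past the threshold by edgeR, and the highest other split gave 8. Since a count of 0 is reached by all 10 splits whatever the data, it says nothing on chance. At an unadjusted p under 0.05 the real split gave 2334 genes and the highest other 2104 (1 split of 10 as high), and DESeq2 called 266 and 185 genes (1 split of 10 as high). For gene lists the real split gave 5 and the highest other 14, with 9 splits of 10 giving as many. The camera p of the ribosomal list alone, at the preset correlation, was 1.47e-25 in the real split (1 split of 10 as small). In the others it was 3.75e-09, 6.08e-08, 3.98e-07, 4.36e-06, 0.00144, 0.00479, 0.00493, 0.111 and 0.846. Small camera p-values of this list thus also arise in splits that mix the genotypes, and 1 of 10 is the least share that these splits allow.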
